A study of Homo sapiens with 6 samples.

How the data were processed

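Expression was measured by RNA sequencing of poly(A) RNA from PANC-1 cells, in 3 libraries labelled as SUV420H2 knockdown by siRNA and 3 labelled as control. Groups were taken from the siRNA label. The labels give no replicate numbers, so replicates were numbered only to name them and nothing was paired, and they name no batch or date. The siRNA sequences, the kind of control and the time after transfection are not given in the sources used here. The extraction text in the labels also speaks of brain cell types that are not among these samples, and markers of such cells were therefore among the gene lists.

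Per the submitters' processing notes, the reads were aligned with GSNAP (version not given in the sources used here) to GRCh38. Per the file headers, each file holds for every gene model the count of reads aligned uniquely to it and the RPKM after a size-factor adjustment by the authors. The annotation release, the method behind the size factor, the strand setting and any filter are not given in the sources used here. In the deposited RPKM, the ratio of count to RPKM was the product of a constant per library and a constant per gene, so the RPKM carry no information beyond the counts, and the deposited counts were used for all tests. Unique alignment leaves out reads shared by near-identical genes, which lowers multicopy genes.

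Each file lists 30727 genes by numeric gene ID. Symbols and coordinates came from the RefSeq annotation of GRCh38.p14 for 27814 IDs and from GENCODE 29 for 37, and 2876 IDs had no symbol. IDs without a symbol held 0.266% to 0.289% of reads and stayed in the tests. No pair of libraries held identical counts, and every pair of replicates differed by more than sampling noise (chi-square over genes with at least 20 reads in the pair), so all were counted as separate libraries. This does not show that they came from separate cultures.

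Totals ran from 20863594 to 25931995 reads in the controls and from 27007534 to 38022772 in the knockdown libraries. Counts were filtered with filterByExpr, which left 15190 genes (minimum count 10, minimum total 15), scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are knockdown over control; SE is that of the log2 fold change. CPM values are scaled by TMM and given as mean ± SD over 3 libraries. The biological coefficient of variation was 0.0550 over all libraries, 0.0779 within the controls and 0.0237 within the knockdown. On counts simulated from the means and library sizes of these controls (14727 genes fitted), the edgeR test recovered 60% of genes changed 1.25-fold, 70% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, and called 0.0734% of unchanged genes. That simulation changed 50 genes at each fold and gave every gene the same dispersion in both groups. In these data 67.3% of tested genes were called and the spread differed between groups, so these shares may not carry over. The exact interval around a count ratio covers counting error only.

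Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The lists were epithelial, mesenchymal, TGF-beta targets, H4K20 and heterochromatin, mitosis, DNA replication, replication-dependent histones, p53 targets, DNA damage response, interferon response, NF-kB and cytokines, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, pancreatic lineage, stemness and drug transport, migration and protease, markers of neurons, astrocytes, microglia and leukocytes, and fibroblasts and endothelium, and 5 families matched by symbol: ZNF genes, clustered protocadherins, cancer-testis families, ribosomal proteins and the mitochondrial genome. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 27 lists. The named genes were KMT5C, KMT5A, KMT5B, CDH1, VIM, ZEB1, FOXA1, OVOL1 and OVOL2; the 6 largest rises and 6 largest falls among genes past the threshold with mean log2 CPM of at least 1 and no overlap between groups, passing over genes without a symbol, RNA genes lacking poly(A) and near-identical multicopy genes; the 4 members of the epithelial and of the mesenchymal list with the smallest p; the 2 such members of every other list; and the 3 genes of highest CPM past the threshold. Members outside this rule that are named beside a list (such as FN1, MUC1, MCM5, FAS and DNMT1) were chosen after their values were seen. Some genes that the rule names are not reported here, and they were not replaced.

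Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, no low-count filter, a minimum mean log2 CPM of 1, the DESeq2 Wald test, limma-voom, edgeR's glmTreat against a 1.5-fold change, removal of a trend on gene length or GC content (a GC value was at hand for 94.5% of tested genes), leaving out each library, camera with an estimated correlation, and fry. Thinning all libraries to 20863594 reads was added after the totals were seen.

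For the closing section, 3′ UTRs and coding sequences came from the GENCODE 29 transcript with the longest 3′ UTR of each gene (at least 50 bases; genes without one were not searched). The log2 fold change, limited to 2 either way, was regressed on the presence of each 6-base word, with length, GC content and expression as covariates, over 10812 genes with mean log2 CPM above 2. Neighbouring genes were compared by Spearman's rank correlation over 12893 protein-coding genes in chromosome order, without clustered protocadherins, mitochondrial genes and hyphenated symbols, with 10000 permutations of the order. Both were tested on simulated data first, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.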

Results

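Poly(A) RNA was sequenced from PANC-1, a human cell line from a carcinoma of the pancreatic duct, after treatment with siRNA against SUV420H2 or as control. SUV420H2, now named KMT5C, is an enzyme that methylates lysine 20 of histone H4, a mark of condensed chromatin. There were 3 libraries in each group. The labels do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. The controls held 25153340, 20863594 and 25931995 counted reads, and the knockdown libraries held 38022772, 27007534 and 29758241. Between 19760 and 21375 genes had at least 1 read in a library. The only comparison the design implies is knockdown against control, which asks which genes differ between cells given siRNA against SUV420H2 and control cells. It cannot part the lowering of SUV420H2 from other effects of the siRNA treatment.

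The targeted gene was lower in all 3 knockdown libraries than in any control. KMT5C (gene ID 84787; GRCh38 chromosome 19, 55339876 to 55348121) had 9.55, 7.23 and 12.7 CPM (reads scaled to library size) in the controls, from 150 to 323 reads per library. The knockdown libraries had 6.03, 6.11 and 5.86 CPM, from 166 to 231 reads. The mean was 9.81 ± 2.72 CPM (SD, n = 3) in the controls and 6.0 ± 0.130 CPM (SD, n = 3) in the knockdown, or 61.2% of the control level. The log2 fold change was −0.72 (SE 0.163, edgeR adjusted p = 0.00227). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 allows. Of the related enzymes, KMT5A, which adds the first methyl group to the same lysine, rose by 0.81 (SE 0.0789, edgeR adjusted p = 4.28e-06), and KMT5B, the closest relative of KMT5C, stood at 0.10 (SE 0.0530, edgeR adjusted p = 0.122) on the log2 scale. The log2 fold change of KMT5C was −0.50 without control replicate 3 (edgeR adjusted p = 0.00021), and the fall did not pass a test against a 1.5-fold change (adjusted p = 0.305; range over all alternatives 4.59e-10 to 0.305). KMT5B passed with a GC content trend removed (adjusted p = 0.00469; range 0.00469 to 1).

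**Figure D1:**
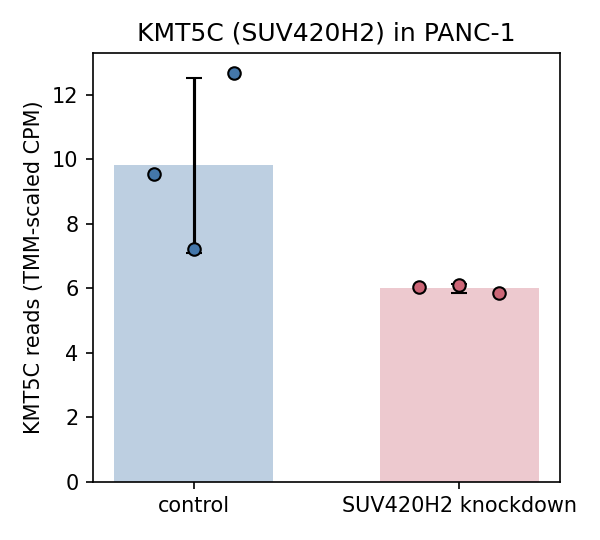
KMT5C level in CPM (vertical axis, scaled by TMM, linear from 0) in the 3 control and 3 SUV420H2 knockdown libraries; bars are group means, points are libraries and error bars are SD. The controls ran from 7.23 to 12.7 CPM and the knockdown libraries from 5.86 to 6.11 CPM.

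Most genes of the epithelial list (28 of 37) were higher in the knockdown cells, some by more than 10-fold, while the mesenchymal filament gene VIM and the repressor ZEB1 were lower. CDH1, which encodes the adherens junction protein E-cadherin (GRCh38 chromosome 16, 68737292 to 68835537), rose from 34.4 ± 0.794 to 378 ± 5.00 CPM (SD, n = 3 each), a log2 fold change of 3.46 (SE 0.0447, 11-fold, edgeR adjusted p = 1.80e-12). SPINT1, an inhibitor of membrane serine proteases, rose from 5.17 ± 0.174 to 235 ± 3.6 CPM (log2 fold change 5.51, SE 0.0566, edgeR adjusted p = 4.21e-13). ELF3, an epithelial transcription factor, rose by 2.94 (SE 0.0578) and DSP, the desmosomal protein desmoplakin, by 2.05 (SE 0.0522) on the log2 scale. Of the 37 epithelial genes tested, 28 rose, 5 fell and 4 did not pass (MARVELD3, EHF, FOXA2 and SPINT2); adjusted over the list alone, the counts were again 28 and 5.

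Among the epithelial transcription factors, FOXA1 rose from 0.877 ± 0.320 to 18.9 ± 1.05 CPM (log2 fold change 4.39, SE 0.153, edgeR adjusted p = 1.93e-09), and OVOL2 rose from 0.199 ± 0.0421 to 1.60 ± 0.373 CPM (2.97, SE 0.329, edgeR adjusted p = 1.10e-05). OVOL1 rose from 1 read in all 3 controls together to 51 in the knockdown libraries (edgeR adjusted p = 6.23e-05), a depth-corrected count ratio of 38.1 with an exact 95% counting interval of 6.53 to 1530. The members that fell were MUC1, a cell surface mucin (−1.83), CDS1 (−1.60), MAL2 (−0.98), ESRP2, a splicing regulator (−0.70), and KRT19, a keratin (−0.32). The list as a group was higher in limma's camera test (adjusted p = 3.91e-22 with the preset correlation, 0.0157 with an estimated correlation), the only list of 27 whose call held with an estimated correlation. That setting gave a larger adjusted p for all 27 lists, also where the estimate lay below the preset. A call lost under it therefore does not show that the members of a list are correlated.

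The mesenchymal genes moved both ways. VIM, which encodes vimentin and was among the 3 most abundant transcripts past the threshold, fell from 5403 ± 348 to 3813 ± 65.6 CPM (log2 fold change −0.50, SE 0.0502, edgeR adjusted p = 5.18e-06), and ZEB1, a repressor of CDH1, fell from 50.2 ± 2.84 to 32.0 ± 0.831 CPM (−0.65, SE 0.0587, edgeR adjusted p = 2.26e-06). Other members went the other way: COL1A1 rose by 2.01 (SE 0.0601), COL3A1 by 4.36 (SE 0.175) and COL5A2 by 0.95 (SE 0.0382), all fibrillar collagens, and ITGA5, a fibronectin receptor subunit, by 1.23 (SE 0.0486). Fibronectin itself, FN1, rose by 2.39, whereas the matrix protein TNC (−0.87), the matrix protease MMP2 (−1.13) and the collagen crosslinking enzyme LOX (−0.46) fell, and COL6A1 (0.03) and COL6A3 (−0.03) did not pass. Among the other transcription factors of the list, SNAI1 rose (0.38), while FOXC1 (−0.97) and FOXC2 (−1.11) fell. SNAI2 (0.61), ZEB2 (0.56) and TWIST2 (−0.28) did not pass. Of 37 members tested, 18 rose, 11 fell and 8 did not pass, with the same counts adjusted over the list alone. The list was higher in camera (adjusted p = 0.0162), a call lost with an estimated correlation (adjusted p = 0.423; range over its camera alternatives 0.00238 to 0.423). The falls of VIM and ZEB1 did not pass a test against a 1.5-fold change (adjusted p = 1 and 0.208; lowest over the alternatives 4.36e-24 for VIM and 3.49e-18 for ZEB1).

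**Figure D2:**
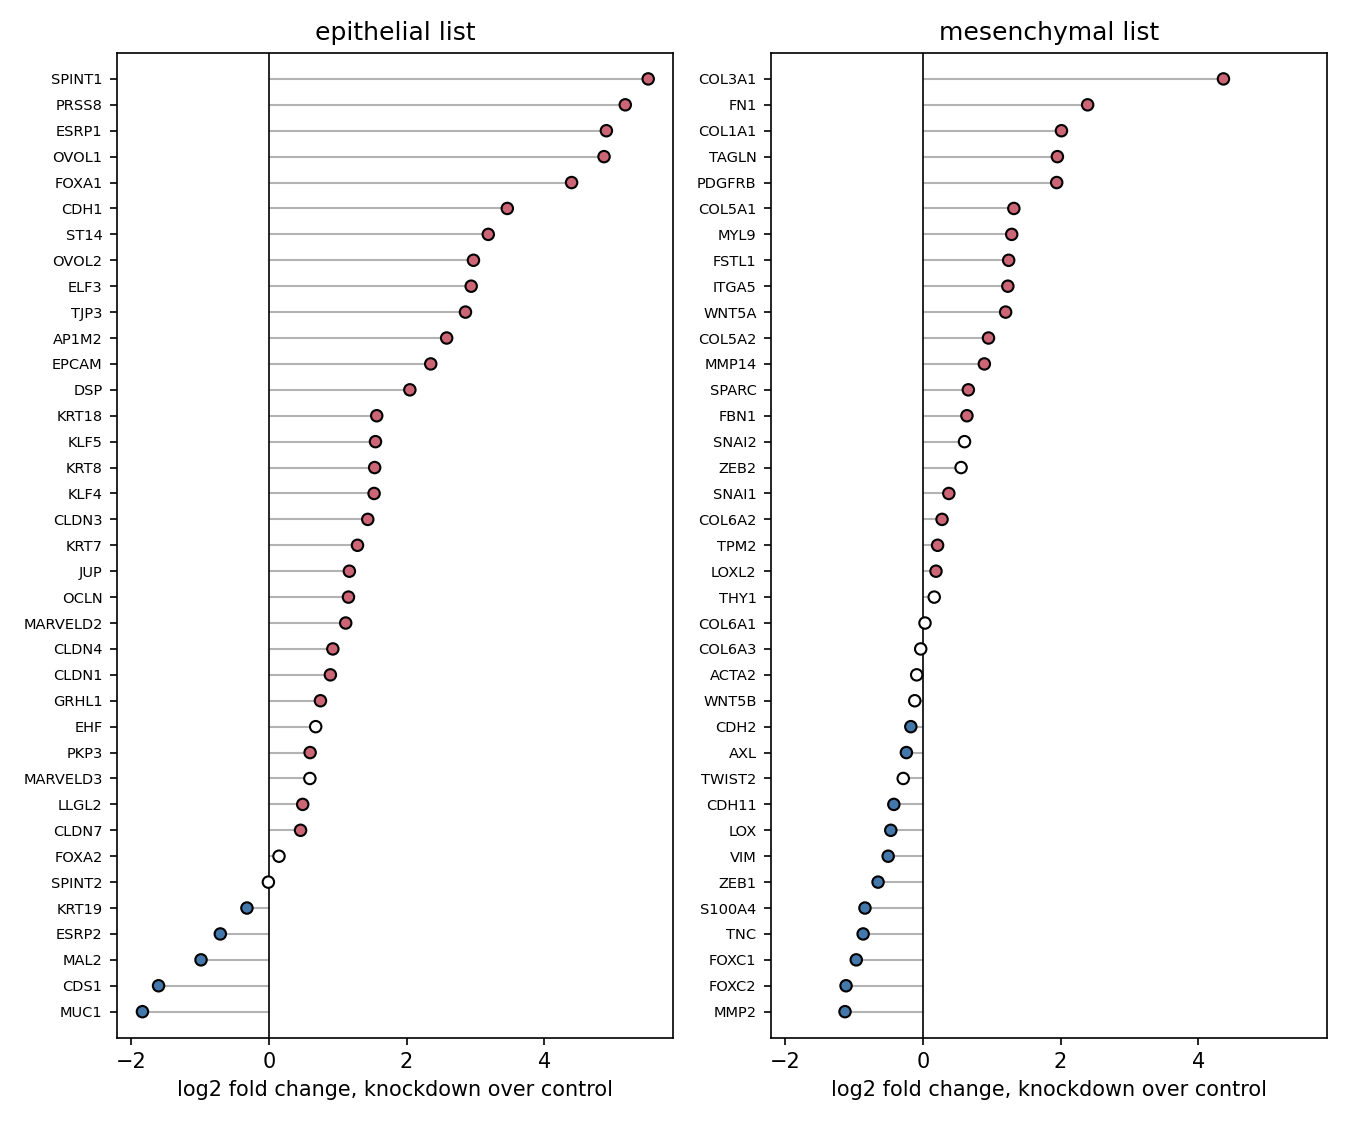
Log2 fold change, knockdown over control (horizontal axis), of each of the 37 tested epithelial genes (left) and 37 tested mesenchymal genes (right). Red points passed an adjusted p of 0.05 and were higher, blue passed and were lower, and white did not pass; SPINT1 stands at 5.51 and MUC1 at −1.83 in the epithelial panel, COL3A1 at 4.36 and VIM at −0.50 in the mesenchymal panel.

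The largest rises by the fixed rule were led by COL2A1, the cartilage collagen (GRCh38 chromosome 12, 47972967 to 48006212), which went from 0.627 ± 0.139 to 218 ± 7.14 CPM (log2 fold change 8.42, SE 0.0916, edgeR adjusted p = 4.21e-13). SLC1A7, a glutamate transporter (6.53, SE 0.193), VIL1, the microvillus protein villin (6.05, SE 0.267), SPINT1, DLL4, a Notch ligand (5.39, SE 0.151), and SPINT1-AS1 (5.26, SE 0.184) followed. SLC1A7 had 8 reads and VIL1 4 reads in the controls together. SPINT1-AS1 is antisense to SPINT1 and overlaps it; the counting is not stated to use strand, so its value is uncertain. The largest falls included THBD, the endothelial anticoagulant receptor thrombomodulin, from 5.18 ± 0.354 to 0.266 ± 0.138 CPM (−4.18, SE 0.219, edgeR adjusted p = 3.18e-08), the noncoding RNA CRMA (−3.57, SE 0.0863), GLTP, a glycolipid transfer protein (−3.30, SE 0.0961), the noncoding RNA LINC01843 (−3.25, SE 0.146) and ENPP1, a nucleotide pyrophosphatase (−3.17, SE 0.102). Besides VIM, the most abundant transcripts past the threshold were ACTG1, cytoplasmic gamma-actin (−0.54, SE 0.0473), and EIF4G2, a translation factor (−0.23, SE 0.0499).

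Across the transcriptome, 10216 of 15190 genes tested (67.3%) differed in edgeR's quasi-likelihood test, 5028 higher and 5188 lower in the knockdown. Counts of list members that rose or fell are to be read against these totals. Of the changed genes, 4900 differed by under 0.5 on the log2 scale, and the median size of the change was 0.52. At least 2-fold changes were found for 1217 higher and 913 lower genes. These counts depended on the filter: 703 and 637 with genes of mean log2 CPM of at least 1, and 1635 and 1056 with no low-count filter. The values of the groups did not overlap for 10829 tested genes (71.3%), against 10% by chance for 3 against 3. The median over all tested genes was −0.01. Tested against a 1.5-fold change, 2998 genes passed, 1606 higher and 1392 lower. The first principal component, 87.1% of the variance, parted the groups; control replicate 3 stood apart on the second (5.99%), and the chi-square per degree of freedom of its counts against the other controls was 11.3 and 13.6, against 1.55 between control replicates 1 and 2 and 1.99 to 2.26 between knockdown libraries. Without it, 11277 genes passed.

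Among the cell cycle and growth control lists, DNA replication and p53 targets were higher in camera only at the preset correlation, and mitosis did not pass. Of the 35 DNA replication genes, 30 rose and 5 fell; CDC6, which loads the replicative helicase, rose by 0.88 (SE 0.0447) and CCNE2, a G1/S cyclin, by 1.49 (SE 0.0825), while the helicase subunits MCM3 (−0.56), MCM5 (−0.77) and MCM6 (−0.55) fell, as did RRM2 (−0.28) and POLA1 (−0.42). The list was higher in camera (adjusted p = 0.000981), but not with an estimated correlation (adjusted p = 0.351). Of the 25 p53 target genes, 14 rose and 3 fell; GDF15, a stress cytokine, rose by 2.02 (SE 0.104) and FBXW7, a ubiquitin ligase subunit, by 1.39 (SE 0.0673), while PLK2 (−0.46), FAS (−1.06) and TP53I3 (−0.17) fell. The camera adjusted p was 0.0162, and 0.423 with an estimated correlation. Mitosis genes went both ways, 14 of 30 up and 6 down, with CCNB1, the mitotic cyclin B1, at −0.90 (SE 0.0420) and CDC25C, the phosphatase that activates its kinase, at 0.75 (SE 0.0554); the list did not pass (camera adjusted p = 0.369).

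Most of the glycolytic and hypoxia-responsive genes tested were lower. Of 29 tested, 22 fell and 4 rose (HK2, ADM, P4HA2 and SLC2A1); the aldolase ALDOC fell from 32.6 ± 2.12 to 6.11 ± 0.306 CPM (−2.42, SE 0.0790, edgeR adjusted p = 1.26e-09) and VEGFA, an angiogenic growth factor, by 1.05 on the log2 scale (SE 0.0543). The list was lower in camera (adjusted p = 0.00223), but not with an estimated correlation (adjusted p = 0.423). Interferon response genes also fell, 15 of 26 against 5 that rose, with the helicase DDX60 at −1.96 (SE 0.0984) and IFIT2 among those higher at 1.29 (SE 0.0644). Their camera adjusted p of 0.0396 was 0.423 with an estimated correlation, and the call was also lost without control replicate 3 (adjusted p = 0.203), with a GC trend removed (0.162), with genes of mean log2 CPM of at least 1 (0.188) and with all libraries thinned to the same depth (0.0759; range over the camera alternatives 0.00763 to 0.423). Of 78 ribosomal protein genes, 51 fell and 2 rose, by small amounts (median −0.23; RPL13A −0.80, SE 0.0548; RPLP0 −0.50, SE 0.0376); their camera adjusted p was 0.0112, and 0.552 with an estimated correlation. These genes have many processed pseudogenes, which can take uniquely aligned reads, so their values are uncertain.

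Of 25 genes of histone H4 lysine 20 methylation and heterochromatin, 11 rose and 7 fell. The list did not pass against other genes (camera adjusted p = 0.416, and 0.604 with an estimated correlation). It was higher on balance when tested against no change (fry adjusted p = 4.19e-05). Many lists that did not pass camera also passed fry, such as cholesterol synthesis (fry adjusted p = 8.38e-05), so this does not set the list apart. DNMT3B, a DNA methyltransferase, rose by 1.34 (SE 0.0718) and HELLS, a chromatin remodeler, by 0.76 (SE 0.0515), while the maintenance methyltransferase DNMT1 fell (−0.51). Of 422 genes named ZNF with a number, many of which encode KRAB zinc finger proteins, 131 rose and 102 fell (camera adjusted p = 0.727); ZNF274 rose by 1.56 (SE 0.0699) and ZNF25 fell to −1.66 (SE 0.0901). Of 47 clustered protocadherin genes 37 rose and 2 fell (camera adjusted p = 0.00226, and 0.423 with an estimated correlation), with the smallest p for PCDHAC2 (0.85, SE 0.0560) and PCDHA12 (0.83, SE 0.0575). Members of the alpha and gamma clusters share their 3′ exons and so their reads, and cannot be taken as separate measurements. Of the cancer-testis families only SYCP3, a synaptonemal complex gene (0.33, SE 0.0896), and SSX2IP (−0.96, SE 0.0591) were tested; SSX2IP is a centrosomal gene matched by its name. The list did not pass (camera adjusted p = 0.369).

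Genes linked to migration, stemness and the pancreas showed large changes in single members. CDA, cytidine deaminase, which inactivates gemcitabine, rose from 0.511 ± 0.121 to 15.3 ± 0.829 CPM (log2 fold change 4.87, SE 0.141, edgeR adjusted p = 5.17e-10), and KLF4, a transcription factor, by 1.53 (SE 0.0634); of 20 stemness and drug transport genes 11 rose and 7 fell (camera adjusted p = 0.267). TIMP2, a metalloprotease inhibitor, rose by 1.67 (SE 0.0387) and ITGA3, a laminin receptor subunit, fell to −1.51 (SE 0.0514), with 15 of 27 migration and protease genes up and 8 down (camera adjusted p = 0.161). AGR2, a disulfide isomerase of secretory epithelia, rose by 1.41 (SE 0.0431) and MNX1, a pancreatic transcription factor, by 1.83 (SE 0.182); of 14 pancreatic lineage genes 7 rose and 3 fell (camera adjusted p = 0.21). TGFBR2, a TGF-beta receptor, fell to −1.03 (SE 0.0434) and LTBP2, a latent TGF-beta binding protein, to −1.18 (SE 0.0469), but 10 of 20 TGF-beta targets rose and 4 fell (camera adjusted p = 0.83).

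The other lists did not pass camera. DNA damage response genes split 10 up and 8 down of 26 (adjusted p = 0.416), with RNF168, a ubiquitin ligase, at 1.05 (SE 0.0656). Unfolded protein response genes split 15 up and 8 down of 25 (adjusted p = 0.346), with ATF3 at 1.77 (SE 0.0540) and DDIT4 at −1.22 (SE 0.0541). NF-kB and cytokine genes split 3 up and 8 down of 16 (adjusted p = 0.307), with NFKB1 at −0.90 (SE 0.0608) and TNFAIP2 at −0.87 (SE 0.0487). Cholesterol synthesis genes split 5 up and 11 down of 24 (adjusted p = 0.341), with DHCR7 at −0.80 (SE 0.0433). Oxidative phosphorylation genes split 3 up and 11 down of 30 (adjusted p = 0.341), with NDUFV1 at −0.94 (SE 0.0516) and ATP5F1B at −0.34 (SE 0.0439). Of 13 mitochondrial genome genes 10 fell and 2 rose (adjusted p = 0.192, and 0.0192 without control replicate 3; range over the camera alternatives 0.0192 to 0.736), with ND6 at −0.51 (SE 0.0474) and COX3 at −0.40 (SE 0.0427). Of 8 replication-dependent histone genes, whose main transcripts lack poly(A), 7 fell and 1 rose (adjusted p = 0.477), with H2AC6 at −1.19 (SE 0.160) and H2BC12 at 0.52 (SE 0.0637).

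Markers of other cell types were mostly below the count filter. Of 17 neuron markers 9 were tested, 3 up and 4 down (camera adjusted p = 0.341), with SYT1 at −2.17 (SE 0.112) and TUBB3 at −1.05 (SE 0.0761). Of 11 astrocyte markers 4 were tested, 1 up and 2 down (adjusted p = 0.946; median −0.14, mean 0.14), with FGFR3 at 1.72 (SE 0.0960) and GLUL at −0.90 (SE 0.0550). Of 16 microglia and leukocyte markers 2 were tested (adjusted p = 0.51), of which CD68, a lysosomal protein, rose by 0.44 (SE 0.0515). Of 13 fibroblast and endothelial markers 2 were tested and both rose (adjusted p = 0.26), ESAM by 2.29 (SE 0.151) from 60 control reads and COL14A1 by 1.21 (SE 0.338) from 17, the latter not in DESeq2 (adjusted p = 0.0559; range over the alternatives 0.00434 to 0.0767). Adjusted over the list alone, counts differed from those given for only 4 lists: DNA damage response (11 up), stemness and drug transport (12 up), oxidative phosphorylation (9 down) and the ZNF genes (127 up, 99 down).

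**Figure D3:**
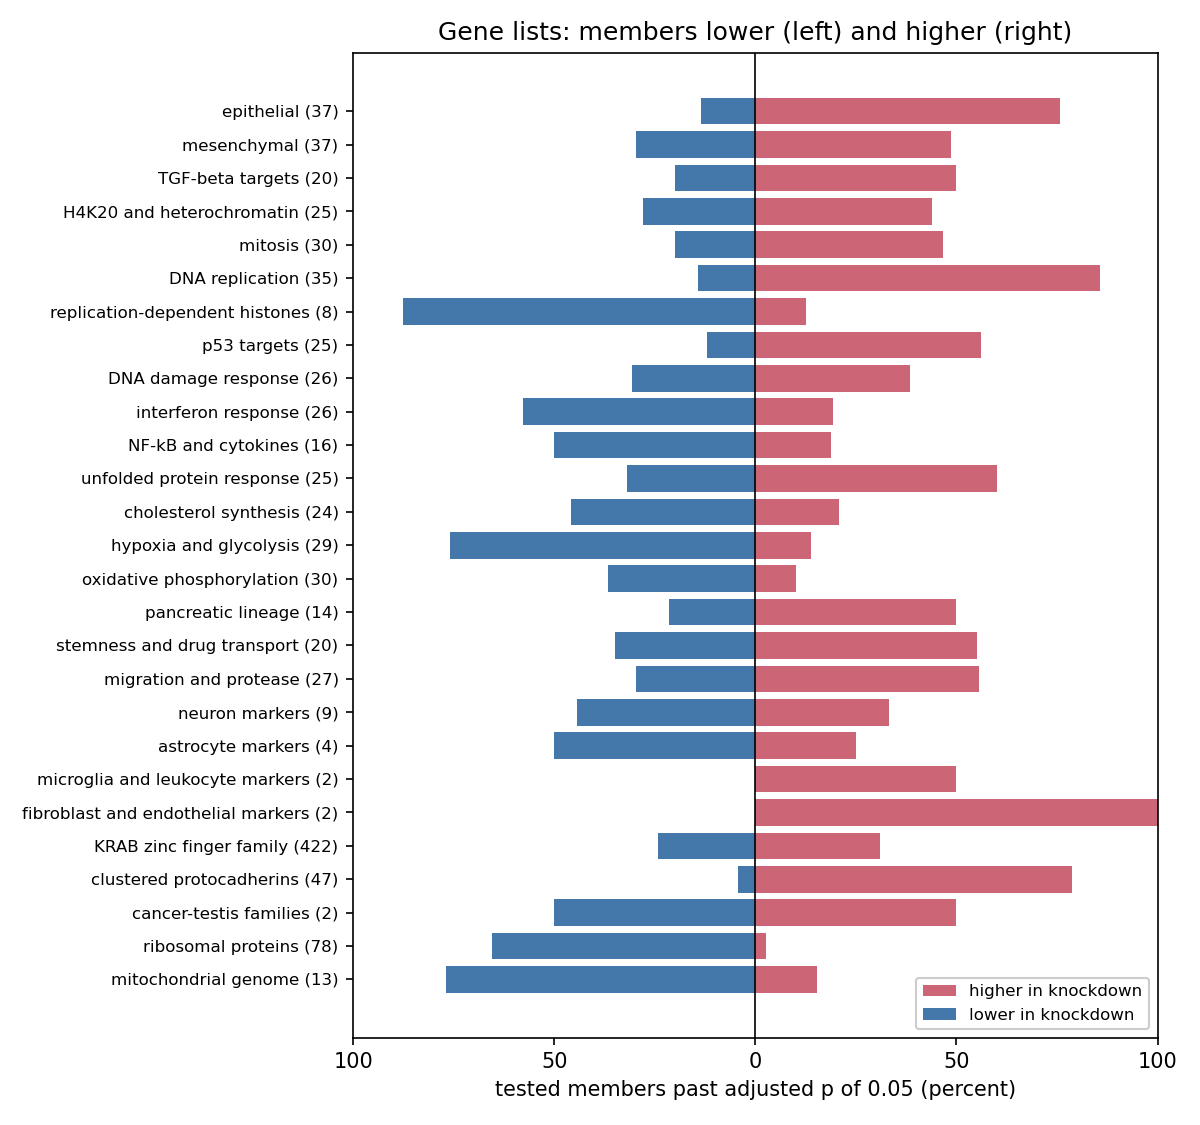
Percent of the tested members of each of 27 gene lists (horizontal axis) that were higher (red, right) or lower (blue, left) in the knockdown past an adjusted p of 0.05; the number tested stands in parentheses. Epithelial genes were 75.7% higher and 13.5% lower, and hypoxia and glycolysis genes 13.8% higher and 75.9% lower. Of all 15190 genes tested, 5028 were higher and 5188 lower.

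The 6-base words AGCACT or AGCACG occur in the annotated 3′ UTR of 20 of the 30 genes under the naming rule that fell and have such a UTR, and of 14 of the 41 that rose. ZEB1 holds 5 copies, GLTP and TGFBR2 3 each and KMT5C 2, ENPP1, ITGA3, LTBP2 and TUBB3 hold 1 each, and VIM, CCNB1, DDX60 and NFKB1 hold none. Over 10812 genes with a 3′ UTR and mean log2 CPM above 2, those with either word were lower in 42.1% and higher in 31.9%, and those with neither were lower in 32.7% and higher in 37.3%. Both words were picked by a scan of these same fold changes, so their excess among genes that fell is not independent support. These shares were not adjusted for 3′ UTR length. SPINT1 and DLL4 lie in the same stretch of chromosome 15, from 40844048 to 40939073.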

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

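The thinned libraries were chosen as an alternative only after the totals were seen; every other alternative was planned. The count of changed genes ran from 8902 to 11219 under 2 other scalings, 2 other filters, the DESeq2 Wald test (9284), limma-voom (10246) and trend removal, from 9184 to 11277 with a library left out, and was 9705 with the libraries thinned. Of the 10216 genes called, 90.4% were called with the same direction by DESeq2 and 99.3% by limma-voom. Testing against a 1.5-fold change, a stricter question by construction, left 2998 genes, 1606 higher and 1392 lower, with 3 epithelial and 5 mesenchymal members lower, and KMT5C at −0.72 no longer passed. With genes of mean log2 CPM of at least 1, which tests fewer genes (12593), 703 were at least 2-fold higher, against 1217. The mesenchymal list gave a camera adjusted p of 0.423 with an estimated correlation (0.0504, against the preset 0.01). The estimate was close to the preset for the epithelial list (0.0108), p53 targets (0.0116) and DNA replication (0.0227). The larger p for these lists therefore does not show that their members are more correlated than the preset. Lists with an estimate below the preset had a larger adjusted p as well. Migration and protease (estimate −0.0231) went from a camera adjusted p of 0.161 to 0.423. Cholesterol synthesis (−0.0313) went from 0.341 to 0.552. These values argue against correlated members as the reason for the larger p under this setting. What else in the setting raised p was not tested. Without 1 library at a time, the log2 fold change of KMT5C ran from −0.88 (without control replicate 2) to −0.50 (without control replicate 3), and the epithelial list stayed higher (largest adjusted p 1.41e-21). Across the alternatives, no call turned its direction: of the values for single named genes, 1226 stayed on their side of the threshold, 15 lost it (14 of them against a 1.5-fold change) and 1 gained it, and of the list tests 375 stayed, 11 lost it and 16 gained it, 15 of these under fry, which does not compare a list with other genes. Another scaling or a trend removed moved the median of all genes by at most 0.026 and the share of higher calls from 49.2% to 51.0%. No paired analysis was possible because the labels give no replicate numbers. Genes with few reads are limited by depth: OVOL1 rested on 1 control read.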

Other observations

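Some genes that lie near each other changed in the same direction; those named here were picked after their values were seen. On chromosome 12 (GRCh38), keratin genes of simple epithelia, KRT8 (1.54), KRT18 (1.57) and KRT7 (1.29), rose with KRT80 (1.86), KRT75 (3.53), KRT81 (2.22), KRT83 (3.07) and KRT86 (1.98) on the log2 scale, where KRT81, KRT83 and KRT86 are near-identical and their values uncertain. Elsewhere on the same chromosome, the lymphocyte receptor genes KLRK1 (3.26), KLRC3 (3.25) and KLRC4 (3.04) and the activation antigen CD69 (3.69) rose, the KLRC genes again being close copies. On chromosome 1, PODN (5.35) and SLC1A7 (6.53) are adjacent, and on chromosome 7 the metalloreductase genes STEAP1 and STEAP2 fell (−2.19 and −2.77). Away from these, the nuclear receptor HNF4A, a regulator of gut and liver epithelium, rose by 2.71.

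The tests of base composition, of falls without either word, of microRNAs, of chromosome segments and of the joint fit below were chosen only after the results they bear on were seen. Of the 10 splits of the 6 libraries, 1 (the real grouping) called 10216 genes by edgeR. The highest other called 0 by edgeR and by DESeq2, with 16 to 186 genes at an unadjusted edgeR p under 0.05. Each other split mixes libraries of both groups, so the group difference widens its spread and few calls are built in. In addition, 10 splits are too few for a share under 0.05, so the splits cannot decide whether the count arose by chance. The knockdown libraries were deeper, but with all libraries thinned to the same depth 9705 genes were called, and with the GC trend removed 11219, which argues against depth or GC content as the whole cause. The labels name no batch, so none was tested; the loss of SUV420H2 itself stays among the open explanations.

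Genes that fell were rich in 2 short words, in the 3′ UTR and also in the coding sequence. Of all 6-base words of the 3′ UTR, AGCACT (z = −11.6, 4970 genes, shift −0.15) and AGCACG (z = −11.1, 1360 genes, shift −0.20) went with the lowest fold changes. Rearrangements of their bases without the shared core AGCAC reached only −7.43 and −7.07, both in words that share 4 bases in a row with the core. This argues against base composition. MicroRNAs with the seed AAGUGC pair with AGCACT and GCACTT (z = −4.71) but have no match to AGCACG. They therefore cannot account for AGCACG, while whether they account for AGCACT was not tested. An off-target effect of an siRNA whose seed pairs with these words may be a candidate explanation, in a design without the siRNA sequences; a seed is read mainly in 3′ UTRs, and the 3′ UTR shift was the larger for AGCACT (difference −3.76 standard errors) but only narrowly for AGCACG (−2.04, and −1.93 in a joint fit). The same words in the coding sequence also went with lower fold changes (AGCACT shift −0.08, z = −5.82; AGCACG shift −0.15, z = −9.28), which speaks against an effect through the 3′ UTR alone, so the explanation stays open. Of genes with neither word in the 3′ UTR, 32.7% were lower, so falls also occurred without these 2 words there. With 67.3% of all tested genes called, a large share was built in, so it cannot decide whether pairing caused a part of the falls. Genes with neither word can also hold other words with the core, such as AGCACA (z = −6.69). Words in the coding sequence of these genes were not counted.

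Neighbouring genes changed together slightly more than chance. The rank correlation of log2 fold changes was 0.102 over 12870 adjacent pairs (permutation p = 0.0001, one-sided, the smallest that 10000 permutations can give; genes are not independent replicates). It was 0.0850 without overlapping pairs, 0.0888 without pairs of related symbols and 0.0722 without either, which argues against shared reads as the whole cause. Without either, it was 0.0834 for pairs closer than 50 kb and 0.0429 for pairs at least 200 kb apart. For genes 10 places apart the correlation was 0.0138, which argues against copy number of long segments. The highest mean over 9 genes, 2.30 at GCHFR to DLL4 on chromosome 15 (40764068 to 40939073), was reached in 1 of 1000 shuffled genomes; it rested on PPP1R14D (5.07), SPINT1 (5.51), DLL4 (5.39), RHOV (2.61) and GCHFR (1.29), while ZFYVE19 (0.49) and VPS18 (0.28) rose little and DNAJC17 (0.17) and C15orf62 (−0.11), which lie among them, did not pass. The lowest mean over 9 genes, −1.47 on chromosome 4, was reached in 2 of 1000 shuffled genomes. It rested mainly on GABRB1 (−5.87), GABRA4 (−4.54) and ATP10D (−1.70), while ATP8A1 rose (0.71) and NFXL1 (0.15) did not pass. A local change of chromatin may underlie the correlation of neighbours, as a hypothesis found in the same data. However, genes that did not move lie between genes that rose. Chromatin was not measured here, and transcripts that run on from a gene into the next were not tested.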
